A study of Solanum lycopersicum with 4 samples.

How the data were processed

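Messenger RNA was sequenced from pools of tomato shoot meristems of 2 genotypes, tmf mutant and wild type, with 2 biological replicates of each. Per the labels' protocols, meristems were fixed in acetone, total RNA was extracted with a PicoPure kit, mRNA was selected on oligo-dT beads, and libraries were size-selected on gels and amplified by PCR. PCR duplicates cannot be told from independent molecules in these values, so counting intervals cover counting error only. The labels name Bowtie 0.12.5 and edgeR among the tools, per the submitters' processing notes. The genome build, the annotation release, the counting tool, strandedness and the treatment of reads that match several genes are not given in the sources used here, so values of genes with close relatives may share reads.

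The deposited table holds 1 signal value per gene and library for 34727 gene identifiers, of which 887 carry the chromosome number 00. In every library the deposited values sum to 10000000, so the authors scaled read counts to a common total. Within each library 100% of the values above 0 were whole multiples of the smallest one, within 1e-06, which returned the reads behind them: 1 read was worth 0.508 and 0.57 in mutant replicates 1 and 2, and 0.353 and 0.435 in wild-type replicates 1 and 2. Total-count scaling lets abundant genes move all others, but the 20 most abundant genes took between 6.18% and 6.6% of the reads in every library. The whole table was used, and no column was left out.

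Because the deposited unit is normalised, the main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(value + 1), over genes with a mean of at least 1 normalised read (1 read in 10000000) in the 4 libraries, with genotype as the only term. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. A fold change on this scale understates the change of genes with low values. Benjamini-Hochberg adjusted p-values without another tool named are from this limma fit. Tests were two-sided, except that the permutation tests of close gene pairs were one-sided, for as many pairs or more. Gene sets were tested with limma's camera, with a preset inter-gene correlation of 0.01 and with an estimated one, and with fry, and adjusted over the 3 lists with at least 3 tested members. The design was chosen before the data were examined; it named edgeR for counts and limma for a normalised unit, and the second case applied. Alternatives on the recovered reads were edgeR 4.0.16 (quasi-likelihood and exact tests), DESeq2 1.42.0 and limma-voom.

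The replicate numbers were tested for pairing. The deviations of same-numbered libraries from their genotype means correlated at -0.109, and the design states no shared batch, so no block was used in the main fit. Replicates of a genotype differed well beyond sampling noise, with a chi-square per degree of freedom of 50.3 in the mutant and 67.8 in the wild type. Their log2 values correlated at 0.971 in the mutant and 0.98 in the wild type, against 0.958 to 0.976 between genotypes. No sequencing batch is given in the labels.

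Neither the table nor the reference table of gene names (assembly SLM_r2.1) pairs these identifiers with names. The 4 gene lists, of 40 identifiers besides TMF, were therefore fixed from published tomato nomenclature before the data were examined, and each pair was tested against the reference table. A name is printed only where the table places a gene with that name, a synonym it lists or an alias from published nomenclature on the chromosome that the identifier states and within 5 percentage points of its relative order there, which held for 33 of 40, with a largest gap of 4.08. For TM5, J2, AN, TKN2, TKN1, TAG1, TM6 and RIN the match was to a listed synonym. EJ2 was matched as MADS1, FA as FALSIFLORA, TAP3 as DEF, FAB as CLV1 and GOB as goblet, so these names rest on nomenclature that the table does not hold. One identifier lay on another chromosome, 2 were out of order and 4 had no entry; these stay in the list tests and are not named. One of the 2 out of order was the identifier fixed for MACROCALYX, so that gene is not reported by name. The identifier listed as TPIB is printed as TPI, the name the table gives on its chromosome. TMF has no entry in the table, and its identifier rests on published nomenclature. A further 16 lists defined by words in gene descriptions, among them markers of leaf, epidermis, vascular tissue and stress, could not be run, as no descriptions were at hand. The shoot meristem list is thus the only tissue marker list tested. Coordinates are not reported.

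Genes were named by a fixed rule: TMF, AN, FA, S, SFT, SP, J, FUL1, FUL2 and TM5 whatever their result, any other list gene past the threshold, and the largest called changes that carry a name and have a mean of at least 50 normalised reads with no overlap between genotypes. For called genes without a name, the 2 largest rises and the 2 largest falls by that size rule are given by identifier.

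The limma and edgeR procedures were tested on simulated data. Counts were drawn independently for each real gene, with the real library sizes and dispersions estimated from the data, and 200 genes were changed. Only genes with a mean of at least 50 normalised reads were changed, so recovery below that level was not measured. For the mutant against wild-type comparison over 21345 simulated genes, limma recovered 97% of genes changed by 2 on the log2 scale and 100% of those changed by 3 or 5, with 14 false calls among 212. edgeR over 18998 genes recovered 95.5%, 100% and 100%, with 10 false calls among 207. In the real data limma did not call AN or FUL2, at log2 fold changes of 6.03 and 2.93. The simulated shares are thus not the power in the real data. Alternatives covered scaling, filtering, pseudocount, the test, a replicate block and leaving out each library. Figures and resampling tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.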

Results

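The transcriptome of shoot meristems was measured by RNA sequencing in tomato (Solanum lycopersicum) plants carrying a mutation in TERMINATING FLOWER (TMF) and in wild-type plants. TMF encodes a nuclear protein of the plant ALOG family. Meristems of both genotypes were taken 8 days after germination, at a stage labelled late vegetative, that is, before the shoot apex forms flowers. Each genotype had 2 biological replicates, and each replicate was a pool of meristems from several plants. The 4 libraries held 19674165 and 17540331 gene-assigned reads in mutant replicates 1 and 2, and 28310492 and 22977411 in wild-type replicates 1 and 2. Between 22885 and 23596 of the 34727 listed genes had at least 1 read in a library. Levels are given as normalised reads, that is, reads per 10000000 gene-assigned reads, and a count of 0 allows a level of up to 1.06 to 1.71 normalised reads, depending on the library. These limits and the intervals given for ratios cover counting error only.

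The mutated gene itself was examined first. TMF (Solyc09g090180.1.1, an identifier that places it on chromosome 9) was almost absent from both mutant libraries, with 6.1 and 6.27 normalised reads, against 1238 and 2224 in the wild type. The mutant mean was 6.19 ± 0.122 (SD, n = 2) and the wild-type mean 1731 ± 697 (SD, n = 2), a 279.9-fold lower level in the mutant. The log2 fold change was -7.85 with a standard error of 0.34 (limma, Benjamini-Hochberg adjusted p = 7.7e-05). The libraries thus separated at this gene as their labels state.

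The comparison of mutant with wild-type meristems asks which transcripts differ at the late vegetative stage when TMF is mutated. Of 21437 genes tested, 28 were higher and 18 lower in the mutant at an adjusted p under 0.05 (limma), and the smallest change among these 46 genes was 1.92 on the log2 scale. EJ2, TM5 and J2, MADS-box transcription factor genes of the floral organ list, were among those that rose, while TMF had the largest negative log2 fold change. In 8 of the 46 genes neither wild-type library held a read, and in 8 others neither mutant library did. edgeR's quasi-likelihood test on read counts recovered from the same values called 53 genes, 35 higher and 18 lower, and 44 genes were called by both tests with the same sign. The number of calls depended on the test: DESeq2 called 212 genes (150 higher and 62 lower) and edgeR's exact test 286 (202 higher and 84 lower), each including the 46. At an unadjusted p under 0.05, limma gave 1329 genes, against 1072 expected by chance, and 1001 of them were higher in the mutant. Without wild-type replicate 1 the count fell to 6 genes, and without wild-type replicate 2 it was also 6, with TMF still called in each case.

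**Figure D1:**
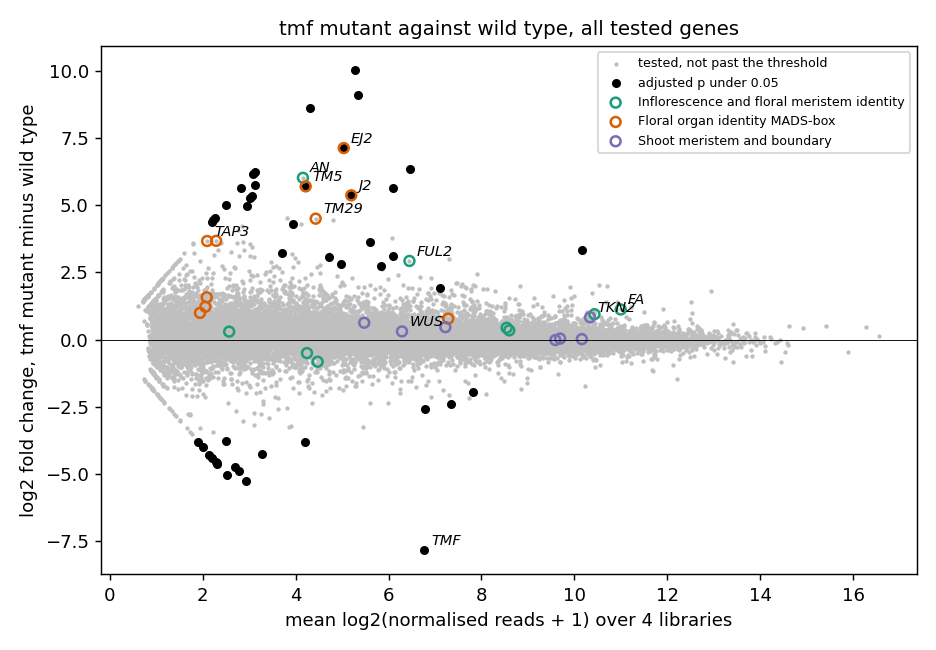
Each point is 1 of the 21437 tested genes, with its mean log2(normalised reads + 1) over the 4 libraries on the horizontal axis and its log2 fold change (tmf mutant minus wild type) on the vertical axis. Black points are the 46 genes with a limma adjusted p under 0.05 and coloured rings are genes of the lists; TMF lies at -7.85, and EJ2, TM5 and J2 lie between 5.37 and 7.14.

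Some genes of the floral organ identity list were read at higher levels in the mutant meristems. Of the 12 floral organ identity MADS-box genes on the list, 3 rose at an adjusted p under 0.05 over all genes tested, 9 did not pass and none fell (limma). All 12 had a positive log2 fold change, from 0.78 to 7.14 with a median of 3.63. In 11 of them both mutant libraries lay above both wild-type libraries, where chance gives 16.7% per gene. These genes share the same 4 libraries and camera estimated a correlation of 0.53 among them, so they are not 12 independent chances. The share over all tested genes is not given here. Adjusted over the list alone, 8 of the 12 passed, all of them higher in the mutant. The list was compiled with knowledge of published work on this mutant, so neither count is independent evidence of its direction. These genes were higher in mutant replicate 1 than in mutant replicate 2 by a median of 0.93 on the log2 scale, and the shoot meristem genes differed between the same libraries by 0.87. Without mutant replicate 1, the counts were 3 over all genes and 7 over the list alone. Without either wild-type library, no gene of the list passed over all genes, while 7 or 8 passed over the list alone.

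On this list the largest log2 fold changes were those of EJ2, TM5 and J2. These are genes of the SEPALLATA class, whose products act with other floral MADS-box proteins. EJ2 (Solyc03g114840.2.1) was at 596 and 253 in the mutant libraries and at 1.41 and 2.18 in the wild type, a log2 fold change of 7.14 ± 0.49 (SE; limma adjusted p = 0.0012). The ratio of its means was 237. TM5 (Solyc05g015750.2.1) was at 311 and 57 in the mutant and at 1.41 and 1.74 in the wild type, a log2 fold change of 5.71 ± 0.73 (SE; limma adjusted p = 0.027). J2 (Solyc12g038510.1.1) was at 561 and 98.6 in the mutant and at 3.89 and 5.66 in the wild type, a log2 fold change of 5.37 ± 0.72 (SE; limma adjusted p = 0.035). All 3 genes lost significance when either wild-type library was left out, with adjusted p from 0.067 to 0.081 for EJ2, from 0.37 to 0.64 for TM5 and from 0.37 to 0.76 for J2, while their log2 fold changes stayed at 5.15 or above in those fits. Their size depended on the mutant library used: without mutant replicate 1 the log2 fold changes of EJ2, TM5 and J2 were 6.52, 4.5 and 4.13, and without mutant replicate 2 they were 7.75, 6.92 and 6.62, with each gene past the threshold in both fits. TM5 and J2 also missed the threshold with limma-voom (adjusted p of 0.26 and 0.27) and without the mean-variance trend (0.12 and 0.15), and J2 with a pseudocount of 0.1 (0.057).

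The other named members of the list are given by value, as they did not pass over all genes, and the 2 members without a printed name did not pass either. TM29, a further SEPALLATA-class gene picked out after its values were seen, was at 226 and 45.6 in the mutant against 3.18 and 3.92 in the wild type (limma adjusted p = 0.061, 0.00043 over the list alone), and it passed in edgeR's quasi-likelihood test on the recovered reads (adjusted p = 0.049) and in limma without mutant replicate 2 (log2 fold change 5.65, adjusted p = 0.018). It missed the threshold without mutant replicate 1 (3.36, adjusted p = 0.085), without wild-type replicate 1 or 2 (0.82 and 0.45), with limma-voom (0.27) and without the mean-variance trend (0.18). RIN, also of the SEPALLATA class, was at 3.05 and 6.27 in the mutant against 1.06 and 2.61 in the wild type, a log2 fold change of 0.99 (limma adjusted p = 0.96). Among the B-class genes, which specify petals and stamens, TAP3 was at 17.8 and 11.4 in the mutant and at 0 and 0.435 in the wild type (adjusted p = 0.06), and TPI (Solyc06g059970.2.1) at 24.9 and 10.8 against 0 and 0.87 (adjusted p = 0.092). The third, TM6, was already present in the wild type at 100 and 139, against 205 and 201 in the mutant (adjusted p = 0.63). TAP3, TPI and TM6 were also picked out after their values were seen. The C-class genes TAG1 and TAGL1, which specify stamens and carpels, stayed at 11.2 or below in every library, with an adjusted p of 0.85 for each.

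As a set, the floral organ genes ranked above the other genes (camera with a preset inter-gene correlation of 0.01, adjusted p = 1.3e-19 over 3 lists). This call did not hold when the correlation was estimated from the libraries (adjusted p = 0.2 with an estimated correlation). The rotation test fry, which asks whether the genes of a set moved one way on balance, is not a permutation test; it gave p = 0.027 and an adjusted p of 0.08.

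The next list holds regulators that specify inflorescence and floral meristems. Of its 12 genes, 11 were tested, none passed over all genes (limma), and 3 passed when adjusted over the list alone, AN, FUL2 and FA, each higher in the mutant. This list carries the same lack of independence as the floral organ list. AN (ANANTHA, Solyc02g081670.1.1), the F-box gene related to UNUSUAL FLORAL ORGANS that is needed for floral identity, was at 435 and 46.7 in the mutant against 0.353 and 2.61 in the wild type. Its log2 fold change was 6.03 ± 0.96 (SE; limma adjusted p = 0.07, 0.0012 over the list alone), and the 2 mutant libraries differed from each other by 3.19 on the log2 scale. FUL2 (Solyc03g114830.2.1), a FRUITFULL-type MADS-box gene, was at 361 and 159.6 against 25.4 and 37, a log2 fold change of 2.93 ± 0.43 (SE; limma adjusted p = 0.055, 0.0012 over the list alone). Without mutant replicate 2, 3 genes of the list passed over all genes, among them AN (log2 fold change 7.62, adjusted p = 0.018) and FUL2 (3.52, adjusted p = 0.037). Without mutant replicate 1 the log2 fold changes were 4.43 for AN (adjusted p = 0.071) and 2.34 for FUL2 (adjusted p = 0.17). FUL2 also passed in edgeR's quasi-likelihood test on the recovered reads (adjusted p = 0.039).

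FA (FALSIFLORA, Solyc03g118160.1.1), the LEAFY homologue of tomato, was abundant in both genotypes, at 3798 and 2388 in the mutant and 1372 and 1399 in the wild type. The ratio of means was 2.23 and the log2 fold change 1.12 ± 0.28 (SE; limma adjusted p = 0.32, 0.015 over the list alone). The remaining named genes of this list did not pass over all genes or over the list alone. J (JOINTLESS, Solyc11g010570.1.1), a MADS-box gene of inflorescence meristems and pedicels, was at 2501 and 1465 in the mutant and 579 and 1708 in the wild type (adjusted p = 0.87). FUL1 (Solyc06g069430.2.1) was at 17.3 and 14.3 against 24.7 and 33.1 (adjusted p = 0.86). S (COMPOUND INFLORESCENCE, Solyc02g077390.1.1), a homeobox gene of inflorescence branching, was at 16.3 and 13.7 against 17 and 27.4 (adjusted p = 1). The set as a whole ranked above other genes with the preset correlation (camera adjusted p = 0.00028), and this was lost with an estimated one (adjusted p = 0.25 with an estimated correlation). The median log2 fold change of the list was 0.44. It fell to 0.16 without wild-type replicate 1 and rose to 0.57 without mutant replicate 1, 0.78 without wild-type replicate 2 and 1.3 without mutant replicate 2.

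**Figure D2:**
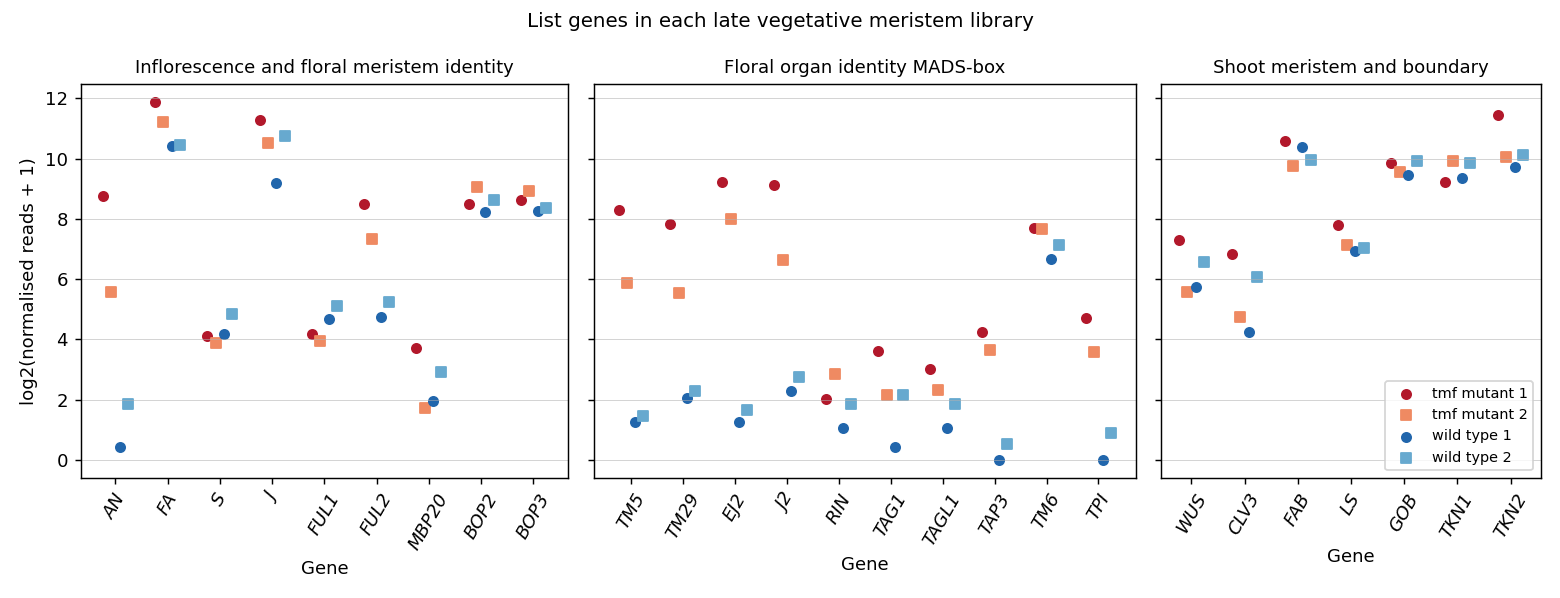
Each symbol is the log2(normalised reads + 1) of 1 gene in 1 library, with mutant libraries in red and orange, wild-type libraries in dark and light blue, and 1 panel for each of 3 gene lists, holding the tested members that have a printed name. EJ2, TM5, J2 and TM29 lie at 5.66 or below on the linear scale in both wild-type libraries and at 45.6 or above in both mutant libraries, while among the 7 shoot meristem genes drawn LS alone has both mutant libraries above both wild-type libraries, as does the 1 tested member not drawn.

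Among genes that maintain the shoot meristem and its boundaries, no difference between genotypes was detected at this replication. None of the 8 genes on that list passed, over all genes or adjusted over the list alone (limma), and their median log2 fold change was 0.38, within a range of -0.02 to 0.88. WUS, the stem cell organiser gene, averaged 102 ± 78 in the mutant and 72.3 ± 28.8 in the wild type (SD, n = 2 each). The KNOX gene TKN2 averaged 1929 ± 1227 against 979 ± 195, and the boundary gene GOB 841 ± 117 against 827 ± 188 (SD, n = 2 each). As a set these genes gave a camera adjusted p of 0.1 with the preset correlation and 0.5 with an estimated correlation. With fry their adjusted p was 0.57. The preset call passed as higher without mutant replicate 2 (adjusted p = 0.00059) and without wild-type replicate 2 (0.037), and turned to lower without mutant replicate 1 (0.27). Mutant replicate 1 had higher levels than mutant replicate 2 in 7 of the 8 genes, and the median log2 fold change of the list was 0.01 without mutant replicate 1 and 0.98 without mutant replicate 2, where 1 gene passed over the list alone. It was 0.06 without wild-type replicate 1 and 0.61 without wild-type replicate 2.

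Most members of the florigen family were not read in these meristems. No read of SFT (Solyc03g063100.1.1), the tomato florigen gene, was found in any of the 4 libraries, which allows a level of at most 1.71 normalised reads in the shallowest one. In all, 6 of the 8 family members had no read in any library. SP (SELF PRUNING, Solyc06g074350.2.1), the TERMINAL FLOWER 1 homologue that keeps shoots indeterminate, was at 21.3 and 61.6 in the mutant and 13.1 and 25.7 in the wild type, and did not pass the test (limma adjusted p = 0.96). SP2G was at 5.08 and 3.99 against 2.83 and 1.74 (adjusted p = 0.98).

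Most of the called genes carry no name in the sources used here. Of the 46, 4 have a name, and 13 further genes with a mean of at least 50 normalised reads and no overlap between genotypes are known only by identifier. The 2 largest rises among these were Solyc06g035940.2.1 and Solyc03g079970.1.1. Solyc06g035940.2.1 had 1143 and 1404 normalised reads in the mutant and 1 read in the 2 wild-type libraries together, a ratio of 6490 with a 95% exact counting interval of 1160 to 256000. Solyc03g079970.1.1 had 903 and 1015 in the mutant and 4 reads in the wild type, a ratio of 1230 with an interval of 478 to 4500. Both had a limma adjusted p of 7.2e-05. The 2 largest falls among the same 13 genes were Solyc12g087830.1.1 and Solyc12g035520.1.1. The first fell from 273 ± 66.8 in the wild type to 44.4 ± 8.16 in the mutant, and the second from 386 ± 112 to 70 ± 9.09 (SD, n = 2 each). Each had a limma adjusted p of 0.023. Both falls lost this call without wild-type replicate 1 and also without wild-type replicate 2.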

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

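The edgeR quasi-likelihood fit with TMM, the TMM-rescaled and RLE-rescaled limma fits, the crossed block, the lists limited to paired identifiers, the list counts without a library and both counts of genes read in 1 genotype only (a minimum of 20 or of 10) were chosen after the data were seen; other settings were planned. The count of 46 genes rose to 212 with DESeq2, 286 with edgeR's exact test, 368 with the replicate block and 219 with the crossed replicate block (mutant 1 with wild type 2, tried because same-numbered deviations correlated at -0.109); all 46 genes were called in each of these, and the cause was not tested. The numbers are not known to pair the samples, so neither block is read as stronger evidence. The count stayed within 1.5 times of 46 under the other 10 settings with all libraries, from 31 (pseudocount of 0.1) to 54 (RLE rescaling). Among these, asking for a fold change of at least 2 could not alter the count, because the smallest called change was 1.92 on the log2 scale. Leaving out 1 library gave from 6 to 61 genes: 35 without mutant replicate 1, 61 without mutant replicate 2, and 6 without either wild-type library; the fits rest on fewer samples, and the lone library of a genotype is assumed to vary like the other pair. TMF kept its direction and its call in all 17 alternatives, with log2 fold changes from -8.27 to -7.43 when 1 library was left out. TMF, the tested genes named by the rule, TM29 and TAP3 kept their sign under every setting run. AN, FUL2, TM29 and TAP3, which missed the threshold, passed it under DESeq2, the exact test and both blocks, and FA under DESeq2 (adjusted p = 0.04) and the crossed block (0.037). FUL2 and TM29 also passed in both edgeR quasi-likelihood fits, FUL2 and TAP3 with no filter, TAP3 without the trend, and AN, FUL2 and TM29 without mutant replicate 2. The camera calls were lost with an estimated correlation, with an adjusted p of 0.25 for the inflorescence and floral meristem list and 0.2 for the floral organ list; they held in the leave-one-out fits, at 2.8e-05 to 0.022 and 8.8e-20 to 4.8e-13. The shoot meristem list went from 0.00059 to 0.79 when 1 library was left out: it reversed to lower without mutant replicate 1 (adjusted p = 0.27), and passed as higher without mutant replicate 2 (0.00059) and without wild-type replicate 2 (0.037). The lists defined by descriptions were not run. Depth limits what can be said of genes under about 3 reads, which is 1.06 to 1.71 normalised reads.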

Other observations

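The tests in this part were chosen after the results they bear on had been seen. For the regrouping of libraries, the minimum and maximum that define genes read in 1 genotype only were also chosen after the data were seen, and only the bounds for reading its counts were set before those counts were known. No biological explanation was tested.

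The higher values of floral organ MADS-box genes in the mutant, of which 3 of 12 passed over all genes, were set against the hypothesis that the mutant pools simply held more meristem tissue. That would raise shoot meristem genes by a like amount. The median log2 fold change was 3.63 for the 12 floral organ genes and 0.38 for the 8 shoot meristem genes, a difference of 3.24, which stayed between 2.98 and 3.42 when 1 library was left out. Taking the lowest mutant library against the highest wild-type library, the medians were 2.64 and -0.47. For these lists, the values argue against more shoot meristem tissue as the whole cause. The floral organ list was compiled with knowledge of published work on this mutant. The comparison was also set after both medians were seen, so it was not a blind test. The leave-one-out and lowest-against-highest values reuse the same lists and libraries, so they add no independent support. Only shoot meristem genes were probed, so an excess of other tissue was not tested. All 4 libraries were taken 8 days after germination, so age does not separate the remaining options. A mutant pool further along towards flowering and an effect of TMF on these genes at the same developmental stage both remain open. They do not exclude each other and were not tested.

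Mutant replicate 1 held more transcripts of the flowering lists than mutant replicate 2, in 18 of 23 genes and by a median of 0.73 on the log2 scale, above the range of -0.52 to 0.12 that holds 95% of 10000 random gene lists matched on mean level. Scaling by TMM moved the ratio of the 2 libraries by only 0.1, which argues against library scaling. The shoot meristem list showed a gap of 0.87 in the same direction, also above its random range of -0.41 to 0.22, so a candidate explanation is that this pool held more meristem tissue. The gap was uneven between genes, at 3.19 for AN, 2.49 for J2 and -0.57 for BOP2 on the flowering lists. On the shoot meristem list it was 2.11 for CLV3 and -0.7 for TKN1, so 1 common shift would not account for every gene. The wild-type libraries showed the same kind of gap, with replicate 2 above replicate 1 by a median of 0.52 for the flowering lists and 0.48 for the shoot meristem list (99.7 and 99.3 percentile of random lists). The random lists were drawn gene by gene, so their genes do not vary together as the list genes do. Camera estimated correlations of 0.24 and 0.53 within the 2 flowering lists and 0.47 within the shoot meristem list. The random ranges and percentiles may thus overstate how unusual these gaps are. Whether mutant pool 1 was also more advanced in development stays open.

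A further pattern is that some genes were read in both libraries of 1 genotype and nearly unread in the other. With at least 20 normalised reads in both libraries of a genotype and at most 1 in both of the other, there were 17 such genes, 10 read in the mutant and 7 in the wild type, on 10 chromosomes; with a minimum of 10 there were 30. The 2 regroupings that mix the genotypes gave 0 such genes, which argues against library-to-library noise, and 0% of the 17 lay within 200 identifiers of TMF, which argues against one chromosome segment carried along with the mutation as the main cause. A hypothesis is that the mutant and wild-type stocks differ in gene content or sequence at scattered places, but no 2 of the 17 lay within 3 identifiers of each other (one-sided permutation p = 1), and since random draws also had a median of 0 pairs, that test cannot decide for differences in blocks. Loss of TMF function is also open for these genes and was not tested.

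Among all 46 called genes there were 4 pairs within 3 identifiers of each other along a chromosome, 1 of them with opposite signs, against a median of 0 and a highest value of 3 in 10000 random draws from the tested genes of the same chromosomes (one-sided permutation p = 0.0001, the smallest these draws can give). The first number after the dot of the identifier was 1 for 34 of the 46 called genes and for 36.4% of the other 21391 tested genes (Fisher's exact test, two-sided, p = 2.8e-07). The draws did not account for neighbours that are close relatives or share reads, and Fisher's test was not matched on level. No cause is drawn from either p-value.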
